A study of Mus musculus with 29 samples.

How the data were processed

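Liver and hindlimb muscle RNA of 16 male mice on 4 diets was sequenced by the authors from TruSeq libraries of Trizol-extracted RNA. Per the series text, 16 livers and 15 muscles were sequenced, and no muscle of soy mouse 1159 is among the libraries. The authors discarded 1 control liver (mouse 1071) and 1 fish muscle (mouse 1125) for their clustering and lower RNA integrity, which leaves 29 libraries. The 8 deposited tables each compare a pair of diets in one tissue and hold 38124 genes by Ensembl identifier. The submitters' processing notes name FastQC and the GRCm38 genome build. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here.

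Per the file headers, the deposited tables give for each library counts of total exon reads, unique exon reads and total gene reads, and RPKM, which are reads per kilobase of exon and per 1e6 reads of the library. The authors' transformed values are log10 of RPKM, per the file headers, and the deposited difference of group means is on the same log10 scale. The authors' p-value per gene comes from a t-test on the transformed values and is not adjusted in the deposited tables. A library in more than 1 table was compared between tables, and 0 of 116 column comparisons differed. Of the 38124 genes 36345 were matched to GENCODE M21 symbols and 1779 were not. The coordinates printed are those of the deposited tables. No fish oil against control or lard against control table was used here; both comparisons were computed from the counts.

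The main measurement was total exon reads per gene. Libraries were grouped by tissue and diet per the labels. The depth was 11315231 to 27106865 exon reads per library, with a median of 15316165. The percent of gene reads outside exons was computed from the authors' total gene and total exon read counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with a minimum count of 10, normalized by TMM, and tested by the quasi-likelihood F test with all 4 diets of a tissue in one fit. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. This left 12788 genes in liver and 13104 in muscle, at a common biological coefficient of variation of 0.212 and 0.235. CPM are means of library values with their SD. SE is an approximate standard error of the log2 fold change, taken as its size divided by the square root of the F statistic. Principal components and scores used log2 CPM with a prior count of 2.

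Fixed lists of pathway genes and of markers of other cell types were tested with camera of limma 3.58.1 at a preset correlation of 0.01, in 222 list tests in liver and 204 in muscle. Counts of members past the threshold are given over all genes and with the p values adjusted over the list alone. The score between control and soy used the genes past the threshold in soy against control, or the 100 genes of smallest p where fewer than 20 passed, and was compared between fish and lard libraries by exact permutation. The covariance of comparisons that share libraries was set beside 20 simulations of unchanged groups, and overlaps beside 10 simulations. Liver and muscle effects were compared by interaction terms in one fit of all 8 groups.

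Named genes were chosen by a rule written before the data were examined. For each of 4 comparisons and each tissue it takes the 5 largest rises and the 5 largest falls past the threshold with a mean of at least 5 CPM and no overlap of the groups. It adds up to 3 members of each list past the threshold, by smallest p. In a list that passes while no member does, the 2 members of smallest p are given as values, and where no gene passes, the 5 genes of smallest p. For tissue differences it takes the 5 genes of smallest p past the threshold at 5 CPM or more. The text names a part of this set, and some genes it selects are not reported here.

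The procedure was tested on simulated data made from the spread of these libraries. Of 100 genes changed 2-fold, 48% to 70% were recovered in the comparisons of both tissues, and 83% to 99% of 100 genes changed 4-fold, with 2.9% to 9% of calls false. For the tissue difference 30% and 64% were recovered. Among 40 simulated lists in each tissue, the raised list was recovered and 0 unchanged lists were called. In the real lists the calls depended on the correlation used by camera. With the preset correlation 77 liver and 67 muscle lists were called, and 2 and 0 of these remained with an estimated correlation. The simulation therefore does not show how often the preset correlation gives false calls in real lists. A simulated fish position of 0.5 was recovered as 0.51 in liver and 0.48 in muscle.

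Alternatives chosen before the data were seen were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a mean of at least 5 CPM, a fit of the compared diets alone, the library number as a block, a test against a 1.5-fold change, the animal as a replicate block for tissue differences, other choices of score genes and scaling, split soy libraries, camera with an estimated correlation, fry, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out the libraries that stood apart, unique exon reads, the percent of reads outside exons as a covariate, and limma-voom with library weights. Alternatives for normalized values alone did not apply, as counts were used. Other groupings of the same libraries were tested with the same fit.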

Results

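Messenger RNA was sequenced from liver and hindlimb muscle of 16 male C57BL/6 mice, an inbred laboratory strain, that were bought at 14 weeks of age and placed on their diets at 4 months. Control mice received 95% of their ad libitum intake (13.6 kcal per day). The other 3 groups were calorie-restricted to 60% (8.6 kcal per day), with soybean oil, fish oil or lard as the fat source. Liver was represented by 3 control, 4 soy, 4 fish and 4 lard libraries, and muscle by 4 control, 3 soy, 3 fish and 4 lard libraries. The 29 libraries held 11315231 to 27106865 reads on annotated exons, with a median of 15316165. In all 39 pairs of libraries within a group the chi-square per degree of freedom was at least 10.95, so no library was a duplicate of another of its group within sampling noise. The series title asks whether omega-3 fat, the characteristic lipid of fish oil, partly returns the expression profile of calorie restriction toward control. The design therefore implies the effect of restriction on the soy diet and the effect of fat source under restriction, each in both tissues.

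A pair of libraries stood apart from the rest of each tissue. In liver these were the soy livers of mice 1073 and 1159. Their first principal component values were 69.0 and 54.5 against -18.2 to -2.01 in the other 13 livers, on a component holding 30.3% of the variance. They also had 5.47% and 5.41% of gene reads outside annotated exons, against 7.91% to 8.92% elsewhere. Their ribosomal protein transcripts had mean log2 CPM (counts per 1e6 library reads) of 8.63 and 8.58, against 7.13 to 7.59 in the other livers. In muscle the control libraries of mice 1071 and 1120 had first component values of -59.9 and -68.1 against -10.6 to 21.6, on a component holding 31.6% of the variance. Their erythroid markers, transcripts of red cells and their precursors, summed to 2361 and 7405 CPM against 485 to 1148 in the other muscles. Neutrophil markers summed to at least 296 CPM in both, against at most 3.22 CPM in the others. Across genes their deviation from the muscle mean had Spearman correlations with exon length of -0.365 and -0.477, against 0.0203 to 0.262 in the other 12 muscles. The plot of both first components shows these 4 libraries away from the libraries of their own diets.

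**Figure D1:**
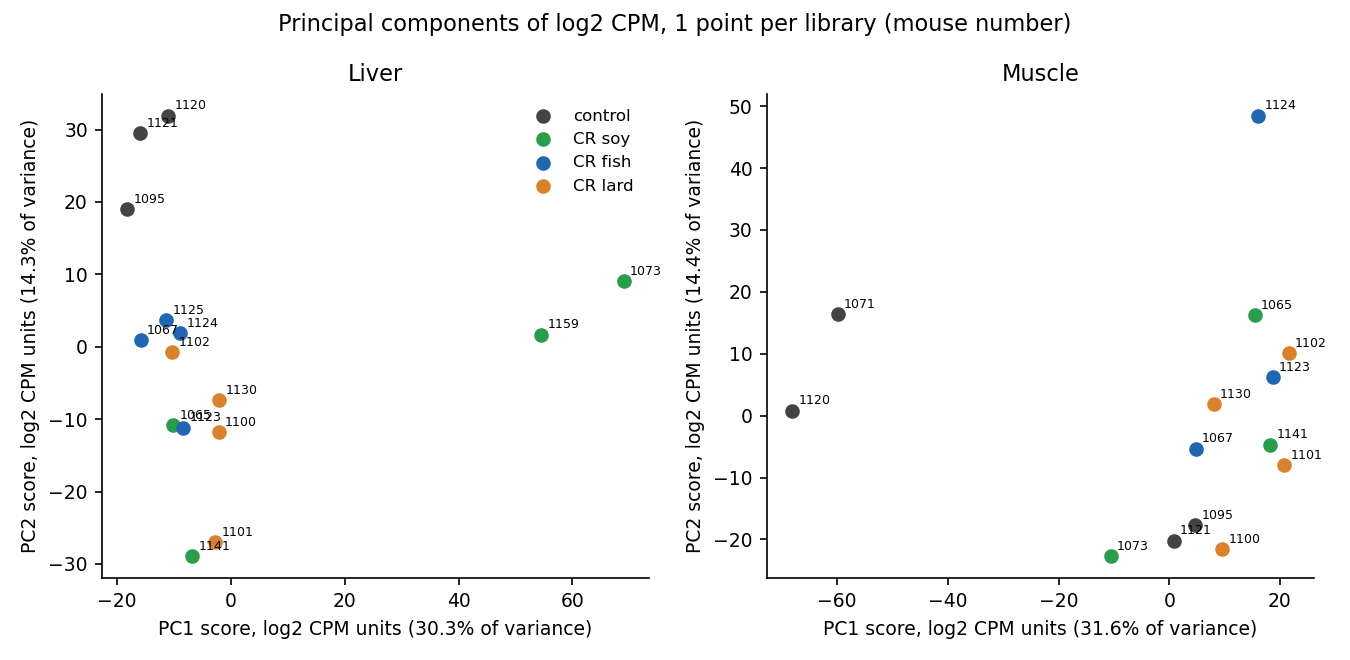
Each point is a library, labelled by mouse number and coloured by diet (control; calorie-restricted, CR, with soy, fish oil or lard), placed by its first and second principal component scores of log2 CPM in liver (left, 15 libraries) and muscle (right, 14 libraries). Soy livers 1073 and 1159 and control muscles 1071 and 1120 lie apart on the first component.

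Calorie restriction on the soy diet was compared with control in liver. Several female-biased transcripts were higher and several male-biased transcripts lower in the soy livers. Cyp2b13 (ENSMUSG00000040583, chromosome 7, 26061495 to 26096196), a cytochrome P450 expressed mainly in female mouse liver, rose by 7.85 ± 1.18 on the log2 scale (fold change ± SE, edgeR adjusted p = 0.00562). Its level was 0.916 ± 0.669 CPM (SD, n = 3) in control and 215 ± 164 CPM (n = 4) in soy livers. Cux2, a transcription factor of female liver, rose by 6.09 ± 1.13 (adjusted p = 0.0166), and so did the steroid hydroxylase Cyp2a4 (adjusted p = 0.0239) and the sulfotransferase Sult2a7, by 3.61 ± 0.64. Among genes with a mean of at least 5 CPM and no overlap of the groups, the 5 largest falls were of major urinary protein genes, which encode pheromone carriers made by male liver. Mup15 (ENSMUSG00000096674, chromosome 4, 61435790 to 61439743) fell by 7.17 ± 0.86 (adjusted p = 0.00172), from 199.9 ± 116.7 CPM to 1.26 ± 1.49 CPM. Mup14 fell by 5.74 ± 0.85, Mup17 by 4.95 ± 0.76, Mup7 by 4.66 ± 1.05 and Mup1 by 4.32 ± 0.94. Only 5.8% to 22.6% of the exon reads of these 5 genes were unique, so the change of each single paralog is uncertain. Cyp4a12a, a fatty acid hydroxylase of male liver, fell by 4.18 ± 0.74, and the glucuronosyltransferase Ugt2b38 fell by 3.98 ± 0.69, from a control level of 4.11 ± 2.67 CPM. Of their reads 66.1% and 75.1% were unique.

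Of 28 male-biased liver genes tested, 8 fell and none rose (0 higher and 22 lower when adjusted over the list alone), with a median log2 fold change of -2.06 and a camera adjusted p of 3.41e-17. Of 24 female-biased genes, 6 rose and none fell (15 higher and 0 lower adjusted over the list alone), with a median of 1.51 and a camera adjusted p of 6.32e-10. Both calls were lost with an adjusted p = 0.335 with an estimated correlation. Cidea and Cidec, which coat lipid droplets and promote their fusion, fell by 6.26 ± 0.88 and 2.07 ± 0.31, Cidea from a control level of 2.96 ± 2.11 CPM. Of 26 cholesterol synthesis genes 1 rose (3 higher and 0 lower adjusted over the list alone). Soat2, which esterifies cholesterol, rose by 0.63 ± 0.14, and Apom, an apolipoprotein of high-density lipoprotein, by 1.12 ± 0.22. Got1, the cytosolic aspartate aminotransferase, rose by 1.34 ± 0.28 among 27 gluconeogenesis and amino acid breakdown genes (9 higher and 0 lower adjusted over the list alone). That list had a median of 0.39 and an adjusted p = 0.335 with an estimated correlation, and the cholesterol list an adjusted p = 0.738 with an estimated correlation. Of the 42 xenobiotic metabolism genes 3 rose and 1 fell (12 higher and 3 lower adjusted over the list alone; adjusted p = 0.708 with an estimated correlation). The 1 that fell was Abcc3, which exports conjugates to blood, by 0.97 ± 0.17. The terminal complement genes C8a and C9 fell by 1.76 ± 0.36 and 1.04 ± 0.21, and the antiviral gene Rsad2 fell by 1.20 ± 0.23. Gsta4, a glutathione transferase, rose by 1.57 ± 0.34, the citric acid cycle gene Idh3a by 0.56 ± 0.13, the replication clamp Pcna (57.8% unique reads) by 0.48 ± 0.11 and the matrix gene Postn by 0.67 ± 0.15. The glycogen-targeting phosphatase subunit gene Ppp1r3g did not pass, at 2.07 ± 0.57 (adjusted p = 0.0746).

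Transcripts of the ribosome, the respiratory chain and the proteasome had higher medians in the soy livers, along with the libraries of mice 1073 and 1159 that held the highest ribosomal levels. Of 76 cytosolic ribosomal protein genes 2 rose, Rpl10 by 1.14 ± 0.25 and Rpl26 by 1.08 ± 0.24 (76 higher and 0 lower adjusted over the list alone), at a median of 0.84. None of 79 nuclear-encoded oxidative phosphorylation genes or 33 proteasome genes passed (67 and 10 higher, 0 and 0 lower, adjusted over the list alone), at medians of 0.66 and 0.44. These lists had adjusted p = 0.696, 0.738 and 0.738 with an estimated correlation. Without the livers of mice 1073 and 1159 their medians were 0.17, 0.03 and -0.006. Only 2.6% of Rpl10 reads and 51.8% of Rpl26 reads were unique, and the cause was not tested. Ndufb4, a complex I subunit with 9.3% unique reads, was at 0.98 ± 0.23 (adjusted p = 0.0508), and the proteasome subunit Psmb3 was at 0.90 ± 0.26 (adjusted p = 0.0855). Of 28 collagen and extracellular matrix genes 1 rose, and the list median was -0.39 (adjusted p = 0.738 with an estimated correlation).

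**Figure D2:**
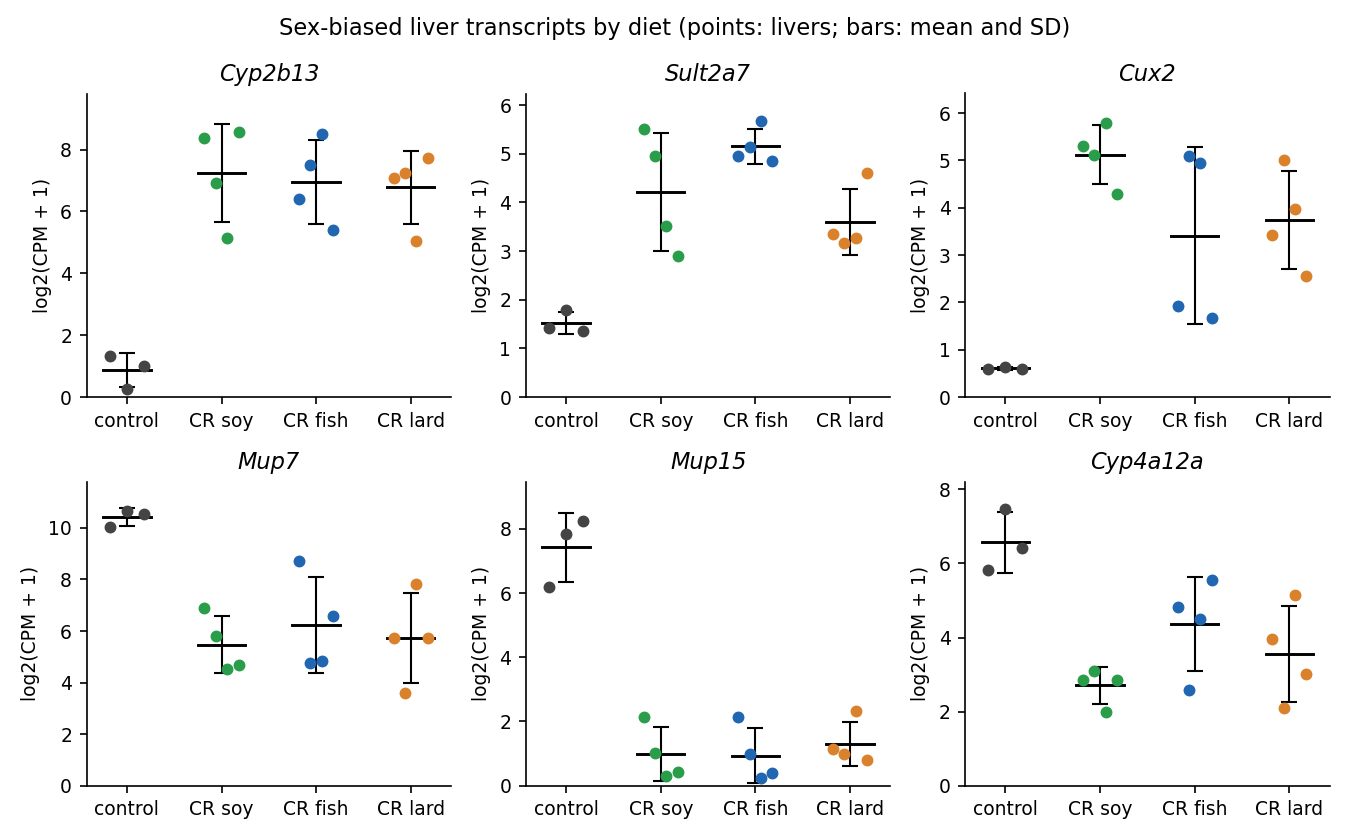
Level of 6 sex-biased liver genes in log2(CPM + 1) by diet, with a point for each liver (3 control, 4 of each restricted diet) and bars for mean and SD. Cyp2b13, Sult2a7 and Cux2 are lowest in control livers, and Mup7, Mup15 and Cyp4a12a are highest there.

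Across 12788 genes tested in liver, 51 were higher and 98 lower in soy than in control by the edgeR quasi-likelihood test at an adjusted p of 0.05. The count was 34 without control liver 1120, 43 without control liver 1121, 64 without soy liver 1159, 1625 without soy liver 1065 and 1330 without soy liver 1141. The balance of directions was not stable: 1017 were higher and 608 lower without soy liver 1065, 885 and 445 without soy liver 1141, and 498 and 368 by the DESeq2 Wald test. The count was 26 without both soy livers that stood apart, 23 of them among the 149. The calls of Cyp2b13, Mup15, Mup14, Mup17, Ugt2b38, Cidea and Cidec held on removal of any single library, with adjusted p values up to 0.0471. Under other settings that of Ugt2b38 was lost in 4 of 11, those of Mup14, Mup17, Cidea and Cidec in 2 and those of Cyp2b13 and Mup15 in 1, and limma-voom with library weights called 0 genes. The other named calls were each lost on removal of at least 1 library, most often control liver 1120 or 1121, and those of Rpl10, Rpl26 and Pcna in 13 of 15 removals.

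Fish oil was compared with soybean oil in restricted livers to ask what the fat source changes. Apoa4, an apolipoprotein of chylomicrons and high-density lipoprotein, fell by 3.44 ± 0.52 on the log2 scale (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459; edgeR adjusted p = 0.0306), from 1223 ± 1006 CPM (SD, n = 4) in soy to 113 ± 45.2 CPM (n = 4) in fish livers. Only 45.4% of its reads were unique, and its exons overlap those of genes on the opposite strand. Adam11, a metalloprotease-family protein without protease activity, rose by 1.82 ± 0.28, from 6.08 ± 1.38 to 21.6 ± 3.32 CPM. Abcc3 rose by 1.11 ± 0.16, from 146 ± 37.1 to 314 ± 28.2 CPM. Sort1, a sorting receptor that handles lipoproteins in the secretory pathway, rose by 1.19 ± 0.19, and Fbxo21, a subunit of a ubiquitin ligase, by 0.82 ± 0.13. Casc4 and Bhlhb9 rose by 1.36 ± 0.19 and 1.31 ± 0.22, the latter sharing exons with Gprasp1 and Gprasp2. Ugt1a6a fell by 0.73 ± 0.12, but its exons are shared with other Ugt1a genes and 5.7% of its reads were unique.

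Metabolic gene groups had lower medians with fish oil, without members past the threshold over all genes. The median of 28 fatty acid and triglyceride synthesis genes was -0.47 (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.48 with an estimated correlation). Its members Me1 and Scd2 were at -0.86 ± 0.22 and 0.76 ± 0.19, both at an adjusted p of 0.106. The median of 27 gluconeogenesis and amino acid breakdown genes was -0.32 (0 higher and 11 lower adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), and Asl, an enzyme of the urea cycle, was at -1.19 ± 0.23 (adjusted p = 0.071). The female-biased gene Hamp2 was at -1.79 ± 0.41 (adjusted p = 0.104). Male-biased genes had a median of 0.70 and female-biased genes of -0.56, with adjusted p = 0.735 and 0.543 with an estimated correlation. Collagen genes had a median of 0.45 (13 higher and 0 lower adjusted over the list alone; adjusted p = 0.513 with an estimated correlation), and Col3a1 was at 0.86 ± 0.17 (adjusted p = 0.0729). Fish liver 1123, which stood apart in Col3a1 and held the most skeletal muscle markers, left it at 0.82 when removed (adjusted p = 0.154). Ribosomal protein and oxidative phosphorylation genes had medians of -0.70 and -0.66, each with an adjusted p = 0.513 with an estimated correlation. Without the soy livers of mice 1073 and 1159 those medians were -0.02 and -0.05.

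The edgeR test called 9 genes higher and 3 lower in fish than in soy livers. No gene passed without fish liver 1067, 1124 or 1125, or without soy liver 1073, so each named call rests on all 4 of these libraries. The count was 1 without fish liver 1123, 5 without control liver 1121 or lard liver 1100, 6 without soy liver 1159, 7 without control liver 1120, 2092 without soy liver 1065 and 1329 without soy liver 1141. Here too the balance turned, to 724 higher and 1368 lower without soy liver 1065, 322 and 1007 without soy liver 1141, and 182 and 631 by the DESeq2 Wald test. The count was 0 without both soy livers that stood apart and 4 with the library number as a block.

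Lard was compared with soybean oil in restricted livers. No gene passed the edgeR test, with 2212 genes at an unadjusted p under 0.05 against 639.4 by chance alone. DESeq2 called 151 genes and limma-voom 0. The genes of smallest p were Atoh8, a transcription factor with a lower level in lard, the nuclear receptor Nr2f6 at -0.70 ± 0.14, the DNA repair gene Ung at -0.93 ± 0.19 and the tight junction gene Cldn3 at -0.81 ± 0.17, all at an adjusted p of 0.229. Only 41.2% of Nr2f6 reads were unique, and its exons overlap those of Ocel1 on the opposite strand. The lipid synthesis lists had higher medians with lard. The 26 cholesterol synthesis genes had a median of 0.36 (2 higher and 0 lower adjusted over the list alone; adjusted p = 0.809 with an estimated correlation). The 28 fatty acid synthesis genes had a median of 0.39 (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.809 with an estimated correlation), and Elovl6, which elongates palmitate, was at 0.88 ± 0.25. Ribosomal protein genes had a median of -0.68, or 0.006 without the soy livers of mice 1073 and 1159. The count of genes past the threshold was 780 without soy liver 1065 and 524 without soy liver 1141.

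Fish oil was compared with lard in restricted livers, where the soy livers enter only through the fit shared by all diets. Lipid synthesis genes were lower with fish oil than with lard, a contrast that does not tell which diet moved them. Elovl6 fell by 1.65 ± 0.26 (ENSMUSG00000041220, chromosome 3, 129532386 to 129638495; edgeR adjusted p = 0.0328), from 374 ± 82.0 CPM (SD, n = 4) with lard to 119 ± 53.2 CPM (n = 4) with fish oil. Acly, which makes cytosolic acetyl-CoA from citrate, fell by 1.57 ± 0.30 (adjusted p = 0.0429), from 442 ± 145 to 148 ± 30.1 CPM. Acacb, an acetyl-CoA carboxylase, fell by 1.44 ± 0.26 (adjusted p = 0.0381), and Pklr, the liver pyruvate kinase, by 1.51 ± 0.25 (adjusted p = 0.0328). Control livers held 143 to 204 CPM of Elovl6 and 166 to 231 CPM of Acly, below every lard liver. Levels of Acacb and Pklr overlapped between control and lard livers. Apoa4 fell by 2.97 ± 0.51, from 885 ± 209 to 113 ± 45.2 CPM. The largest rises were Adam11 at 1.72 ± 0.28 and Cyp3a11, a cytochrome P450 of drug and bile acid hydroxylation, at 1.22 ± 0.20, from 956 ± 190 to 2219 ± 259 CPM. Fbxo21 rose (adjusted p = 0.0223), as did Casc4 by 0.99 ± 0.18 and Abcc3 by 0.92 ± 0.16. Chrna4, a nicotinic receptor subunit, fell by 2.17 ± 0.41, the class I histocompatibility gene H2-Q1 by 1.87 ± 0.31 and the channel gene Hcn3 by 1.72 ± 0.30. The exons of Hcn3 overlap those of Pklr on the opposite strand, and the strand setting of the counts is not given in the sources used here, so the change of Hcn3 is uncertain.

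Of 28 fatty acid and triglyceride synthesis genes, 3 fell and none rose (1 higher and 17 lower adjusted over the list alone), at a median of -0.79 and a camera adjusted p of 7.09e-20. This call held at an adjusted p = 0.00839 with an estimated correlation. Of 27 gluconeogenesis and amino acid breakdown genes none passed over all genes (0 higher and 14 lower adjusted over the list alone), at a median of -0.47 and an adjusted p = 0.0105 with an estimated correlation. In that list Got1 was at -1.26 ± 0.25 (adjusted p = 0.0632). These were the 2 of 222 liver list tests that passed with an estimated correlation. Cholesterol synthesis genes had a median of -0.57 (0 higher and 4 lower adjusted over the list alone; adjusted p = 0.222 with an estimated correlation). The 47 targets of the nuclear receptor PPARα and genes of fatty acid oxidation had a median of 0.27 (adjusted p = 0.562 with an estimated correlation). Among them Cpt1a, which admits fatty acids to mitochondria, was at -0.48 ± 0.15 and Cyp4a31 at 1.60 ± 0.51. The 13 mitochondrially encoded genes had a median of -0.34 (0 higher and 5 lower adjusted over the list alone; adjusted p = 0.268 with an estimated correlation). Skeletal muscle markers had a median of 1.85 (adjusted p = 0.592 with an estimated correlation), and 1 library, fish liver 1123, held 3488 CPM of them against 216 to 513 CPM in the other 14 livers. B and plasma cell markers had a median of 0.72 (adjusted p = 0.346 with an estimated correlation).

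**Figure D3:**
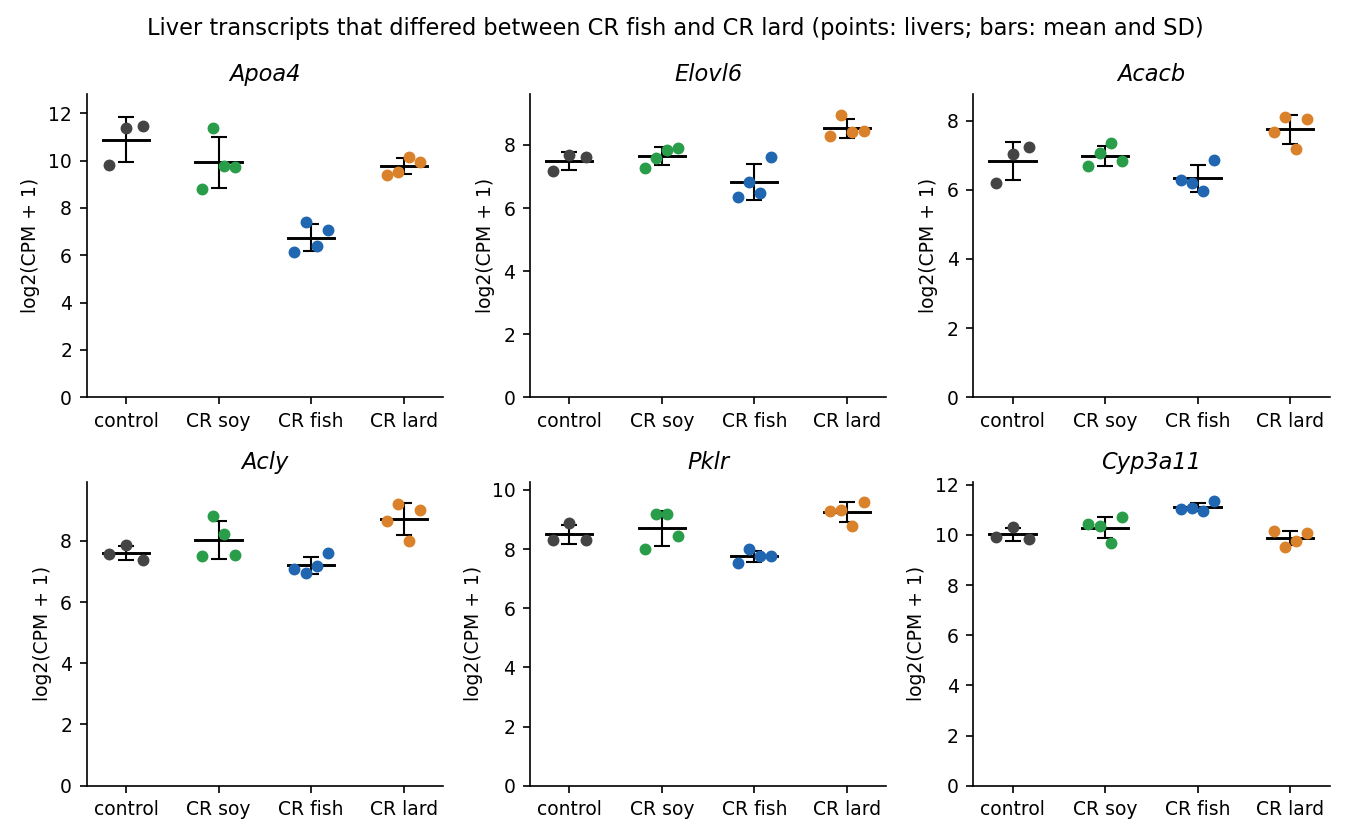
Level of 6 liver genes in log2(CPM + 1) by diet, with a point for each liver (3 control, 4 of each restricted diet) and bars for mean and SD. Apoa4, Elovl6, Acacb, Acly and Pklr are lower and Cyp3a11 is higher in fish oil than in lard livers.

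The edgeR test called 9 genes higher and 17 lower in fish than in lard livers. Of the calls against soy, 5 higher and 1 lower were shared with the calls against lard, where independent lists would share 0.00633 and 0.00399. In 10 simulations of unchanged groups 0 were shared, but such groups leave few calls to share, so this gives no baseline. The fish libraries enter both comparisons, so the overlap is not a count of independent findings. No gene passed without fish liver 1067, 1123 or 1124 or without lard liver 1101, so each named call rests on these 4 libraries. The count was 13 without fish liver 1125 or lard liver 1102, 7 without lard liver 1100, 4 without lard liver 1130, 17 without control liver 1120 or 1121, 43 without soy liver 1073 and 41 without soy liver 1141. It was 98 without both soy livers that stood apart and 136 in a fit of the fish and lard livers alone.

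Fish oil and lard were each also compared with control livers. The edgeR test called 10 genes higher and 39 lower with fish oil, and 23 higher and 42 lower with lard. Male-biased genes again had lower medians: 2 of 28 fell with fish oil (0 higher and 15 lower adjusted over the list alone) at a median of -1.31, and 3 fell with lard (0 higher and 21 lower adjusted over the list alone) at -1.74. Female-biased genes had medians of 0.67 and 0.84, with 3 and 5 of 24 members higher. Estimated correlations gave adjusted p = 0.528 for both lists with fish oil and adjusted p = 0.0786 for both with lard. Cholesterol synthesis genes had a median of 0.86 with lard, where 2 of 26 rose (13 higher and 0 lower adjusted over the list alone; adjusted p = 0.0786 with an estimated correlation). With fish oil the median was 0.18 and 1 rose (adjusted p = 0.895 with an estimated correlation). The difference between both diets is the comparison of fish oil with lard given above. Of the soy calls against control, 7 higher and 25 lower were also called with fish oil, and 14 higher and 32 lower with lard. Independent lists would share 0.0399, 0.299, 0.0917 and 0.322. Simulated unchanged groups against the same controls shared 0, but leave few calls to share, so this gives no baseline. The 3 control livers enter every one of these comparisons and were too few to split, so the overlap is not a count of independent findings. The fish count was 18 without control liver 1120, 15 without 1121, 27, 25 and 22 without fish livers 1067, 1123 and 1124, and 81 without soy liver 1073. The lard count was 39, 23 and 13 without control livers 1095, 1120 and 1121, and 12 and 20 without lard livers 1100 and 1101. Without both soy livers that stood apart the counts were 137 and 236.

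The position of each fish and lard library between control and soy was scored to ask whether fish oil moved expression back toward control. The liver score used the 149 genes that differed between soy and control, scaled so that the control mean is 0 and the soy mean is 1. As these genes were chosen in the same libraries, other diets fall short of 1 by selection alone: in simulated data a lard position of 1 came out as 0.96 in liver and 0.94 in muscle. Fish and lard were therefore compared only with each other. Fish livers scored 0.693 ± 0.087 (SD, n = 4) and lard livers 0.795 ± 0.129 (n = 4). The difference of -0.101 was within the spread (two-sided exact permutation p = 0.229 over 70 splits, of which the smallest possible is 0.0286). It was -0.019 without control liver 1095, -0.058 without lard liver 1101, -0.064 without soy liver 1159, -0.157 without fish liver 1123 and -0.161 without lard liver 1102, and passed on no removal. In muscle no gene passed, so the 100 genes of smallest p were used. Fish muscles scored 0.833 ± 0.074 (n = 3) and lard muscles 0.714 ± 0.048 (n = 4), a difference of 0.119 (exact permutation p = 0.0857 over 35 splits). In muscle the difference passed at an exact permutation p = 0.0286, the smallest the splits allow, without control muscle 1071 (0.177), control muscle 1095 (0.099) or soy muscle 1141 (0.153). It was 0.065 without soy muscle 1073 (exact permutation p = 0.314), 0.069 without control muscle 1121 (p = 0.114) and 0.263 without fish muscle 1067 (p = 0.0667). The muscle difference was 0.205 over the score genes lower in soy (exact permutation p = 0.0571) and 0.003 over those higher in soy (p = 0.886).

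**Figure D4:**
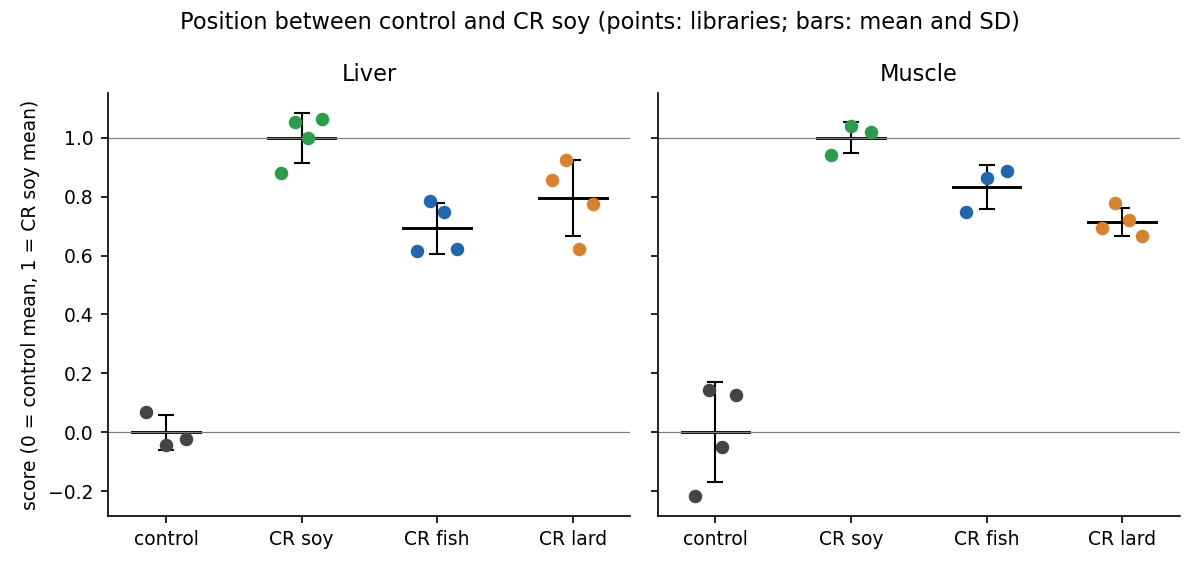
Score of each library between the control mean (0) and the soy mean (1) by diet, in liver (left, 15 libraries) and muscle (right, 14 libraries), with bars for mean and SD. Scores of fish oil and lard libraries overlap in both tissues.

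The soy libraries enter both soy against control and fish against soy, which alone gives opposite fold changes across genes. In liver the correlation across 12788 genes, which are not independent replicates, was -0.661 and the covariance -0.132, against -0.459 and -0.034 in simulations of unchanged groups. The simulations gave all livers the same spread for a gene. The measured spread of the soy livers alone gives a covariance of -0.0582. With the soy livers split so that each contrast used its own pair, the covariance averaged -0.0737 (range -0.106 to -0.0113) and the correlation -0.32. The covariance was -0.0113 and -0.0221 with soy livers 1073 and 1159 in the same pair, and -0.106 to -0.0956 with 1 in each pair, so the average depends on these livers. For lard against soy the covariance was -0.103 and averaged -0.045 with split soy livers (range -0.0821 to 0.0137), at 0.0137 and 0.0104 with both of these livers in the same pair. In muscle the correlation of soy against control with fish against soy was -0.195 and the covariance -0.0252, weaker than the simulated -0.534 and -0.0593. Sharing the 4 control muscles, soy and fish against control had a covariance of 0.164 against a simulated 0.0444, and 0.101 on average with split controls (range 0.0471 to 0.141). For soy and lard against control these values were 0.148, 0.0441 and 0.0844 (range 0.0115 to 0.123). The measured spread of the control muscles alone gives a covariance of 0.0638 for both diets. With control muscles 1071 and 1120 in the same pair the covariance was 0.0498 and 0.0471 for fish and 0.0525 and 0.0115 for lard, the lowest of the splits.

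In muscle, soy was compared with control. No gene passed the edgeR test over 13104 genes, while 2285 had an unadjusted p under 0.05 against 655.2 by chance alone. DESeq2 called 242 and limma-voom 0. The gene of smallest p was Sh3rf2 (ENSMUSG00000057719, chromosome 18, 42053667 to 42158960), a scaffold ubiquitin ligase, at 1.43 ± 0.20 (adjusted p = 0.0516), with 26.8 ± 4.10 CPM (SD, n = 4) in control and 72.4 ± 16.2 CPM (n = 3) in soy muscles. It was followed by Adhfe1 at 0.91 ± 0.16, the phospholipase Pla2g4e at 0.78 ± 0.14, the valine catabolism gene Aldh6a1 at 0.81 ± 0.14 and the sarcomere protein gene Igfn1 at -4.54 ± 0.83, all at an adjusted p of 0.137. Of these, Adhfe1 and Aldh6a1 have exons that overlap a gene on the opposite strand.

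Immune and matrix lists had lower medians in soy muscles. The 8 class II antigen presentation genes had a median of -0.85 (0 higher and 0 lower adjusted over the list alone), with Cd74 at -1.23 ± 0.51 (adjusted p = 0.257). The 29 collagen and extracellular matrix genes had a median of -0.53, with Col6a2 at -0.88 ± 0.33 (adjusted p = 0.229). The 4 B and plasma cell markers tested had a median of -2.69 (0 higher and 4 lower adjusted over the list alone). Among them Ighm, the IgM heavy chain, was at -1.78 ± 0.44 (adjusted p = 0.14), with 206 ± 85.5 CPM in control and 60.2 ± 23.9 CPM in soy muscles. Cell cycle genes had a median of -0.76 (0 higher and 7 lower adjusted over the list alone), with the mitotic genes Aurka and Tpx2 at -1.17 ± 0.30 and -1.24 ± 0.33. Oxidative phosphorylation genes had a median of -0.26 and heat shock genes of -0.32 (0 higher and 4 lower adjusted over the list alone), with the chaperone Hsph1 at -0.50 ± 0.12. Circadian clock genes had a median of 0.27, with Per3 (43.5% unique reads) at 1.11 ± 0.32 and Nr1d2 at 0.51 ± 0.16. Each of these lists had an adjusted p = 0.765 with an estimated correlation. Control muscles 1071 and 1120 also held the most erythroid and neutrophil marker reads and had the exon length trend given above. Without them the medians were 0.56 for the 3 B and plasma cell markers then tested, 0.09 for cell cycle genes and -0.01 for oxidative phosphorylation genes, but -0.73 for class II and -0.57 for collagen genes. The count of genes past the threshold was 9 without control muscle 1095, 9 without control muscle 1121, 1 without control muscle 1120, 1 without fish muscle 1124, and 2 without both 1071 and 1120.

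Fish oil and lard muscles had lower medians than control in immune and matrix lists. With lard, class II genes had a median of -1.46 (0 higher and 7 lower adjusted over the list alone), collagen genes -0.77 (0 higher and 11 lower adjusted over the list alone) and macrophage markers -1.12 (0 higher and 6 lower adjusted over the list alone), each with an adjusted p = 0.574 with an estimated correlation. With fish oil, class II genes had a median of -1.19 and macrophage markers -0.98 (0 higher and 5 lower adjusted over the list alone for each), and collagen genes -0.60 (0 higher and 0 lower), each with an adjusted p = 0.735 with an estimated correlation. Without control muscles 1071 and 1120 the medians of class II, collagen and macrophage genes were -1.21, -0.76 and -0.90 with lard and -0.99, -0.65 and -0.78 with fish oil. Control muscle 1120 held 417 CPM of macrophage markers, against 214 to 229 CPM in the other controls. One gene passed with fish oil: Chia1, a chitinase, fell by 2.52 ± 0.29 (edgeR adjusted p = 0.00655). This gene falls outside the rule for named genes and was chosen after its values were seen. No gene passed with lard, where 2263 had an unadjusted p under 0.05, DESeq2 called 318 and limma-voom 0. The call of Chia1 was lost without fish muscle 1123 or 1124, when the count was 0. The fish count was 69 without control muscle 1095, 57 without fish muscle 1067 and 2 without control muscle 1120. The lard count was 26 without control muscle 1095, 28 without control muscle 1121, 3 without soy muscle 1065 and 1 without fish muscle 1124.

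Fat source left no gene past the edgeR threshold in restricted muscle. Unadjusted p values under 0.05 numbered 288 for fish against soy, 400 for lard against soy and 541 for fish against lard, below the 655.2 expected by chance. DESeq2 called 0, 0 and 14 genes and limma-voom 0 in each. In simulated data the test recovered 48%, 57% and 56% of 2-fold changes and 86%, 87% and 89% of 4-fold changes in these comparisons. Stress response genes were among those of small p in fish against lard, where the smallest adjusted p was 0.236. Trib3, a pseudokinase of the integrated stress response, was at 4.17 ± 0.89, Psat1, an enzyme of serine synthesis, at 3.42 ± 0.71, and Sesn2, a stress-induced regulator of growth signalling, at 2.67 ± 0.60, all at an adjusted p of 0.525. The 27 unfolded protein and integrated stress response genes had a median of 0.29 (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.908 with an estimated correlation). These transcripts were highest in 1 library, fish muscle 1124, with 49.6 CPM of Trib3 against at most 12.6 CPM in the other muscles. The same library held 288 CPM of keratinocyte markers, against 3.64 to 56.5 CPM in the others. The potassium channel gene Kcnj12 was at -0.89 ± 0.18 and Arhgef2, an exchange factor of small GTPases, at 1.67 ± 0.36. In fish against soy the hormone gene Fgf21 was at 4.05 ± 1.31, and in lard against soy the matrix proteoglycan gene Dcn was at -0.69 ± 0.18, both at an adjusted p of 1. In lard against soy, Schwann cell and nerve markers had a median of -0.99 and cartilage, bone and tendon markers of -1.18, each with an adjusted p = 0.667 with an estimated correlation. The count for fish against lard was 31 without fish muscle 1067.

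The effects of diet in liver and muscle were compared directly by an interaction term over 14150 genes. For soy against control 103 genes differed between tissues, 60 with the higher change in liver and 43 with the lower. Osbpl3, an oxysterol-binding protein relative, had a log2 difference between tissues of -3.64 ± 0.56 (edgeR adjusted p = 0.00795), with -3.33 in liver and 0.33 in muscle. The difference was 6.94 ± 1.22 for Cux2, -3.84 ± 0.68 for Scara5, a ferritin receptor, -1.52 ± 0.29 for the sulfatase Arsg and -0.90 ± 0.15 for the galectin Lgals8. For fish against lard 6 genes differed, among them Acox2, a bile acid synthesis enzyme of peroxisomes, at -3.32 ± 0.60, Faah, which degrades fatty acid amides, at -1.52 ± 0.25, and Fbxo21 at 1.20 ± 0.22. No gene differed for fish against soy (1695 at an unadjusted p under 0.05) or lard against soy (1307) by edgeR, the one tool used for this test. With the animal as a replicate block, which needs animals with both tissues, 3 genes differed for soy against control, 2 of them among the 103, and 0 for fish against lard; the same animals without the block gave 7 for soy against control. Every single removal moved the count of 103 by more than 1.5-fold, from 3 without liver control 1120 to 1644 without liver soy 1141, and 1 gene remained past the threshold without the 4 libraries that stood apart. The call of Osbpl3 held on every single removal, with adjusted p values up to 0.0478, but was lost with the animal as a replicate block and without the 4 libraries that stood apart, 2 of 6 other settings, while those of Lgals8, Cux2, Scara5 and Arsg were lost in 1, 3, 4 and 5 of 14 removals. For fish against lard the count was 0 without fish liver 1067, fish muscle 1124, lard muscle 1100 or lard muscle 1101, so each call rests on these 4 libraries. It was 2 without fish liver 1123 or 1124, lard liver 1101 or 1102 or lard muscle 1102, 3 without lard muscle 1130, 10 without fish liver 1125 and 41 without fish muscle 1067. The call of Acox2 was lost in 11 of 15 removals, that of Fbxo21 in 10 and that of Faah in 4.

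The authors' deposited tables give a p-value per gene from pairwise comparisons. Values under 0.05 numbered 1346 for soy against control, 1802 for fish against soy, 880 for lard against soy and 2791 for fish against lard in the authors' deposited tables of liver. The numbers in the authors' deposited tables of muscle were 799, 386, 935 and 1185 in the same order. After Benjamini-Hochberg adjustment of these deposited p-values, 27 genes passed for fish against lard in liver and 0 in each of the other 7 tables.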

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

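The explanations tested after the result was seen are the soy diet and library size for the livers that stood apart, marrow or blood cells and calorie restriction for the control muscles, and the fish diet and skin cells for mouse 1124. The predictions for the other explanations were written first.

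Groups were tested for a single outlying sample by Dixon's gap ratio, which chance alone passes in about 1 in 20. By chance 2.6 flags were expected among marker sums, 7.7 among named genes and 1.8 among library measures. A sample lay far from the other 3 of its group in 12 of 240 groups, which is near the number expected by chance. Among marker sums these were macrophage markers in control muscle 1120 (gap ratio 0.923) and in fish liver 1124 (0.852), neutrophil markers in fish liver 1124 (0.868), skeletal muscle markers in fish liver 1123 (0.945), erythroid markers in lard liver 1130 (0.994) and cartilage, bone and tendon markers in lard muscle 1130 (0.831). Among named genes they were Ugt2b38 in soy liver 1065 (0.847), Eno1, Col3a1 and Myh4 in fish liver 1123 (0.876, 0.937 and 0.956), Serpina1e in fish liver 1067 (0.851) and Ppargc1a in lard muscle 1101 (0.832). Fish liver 1123 thus held the myosin gene Myh4 along with its skeletal muscle markers.

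Effects that differed between liver and muscle were found by the interaction test for 103 genes in soy against control and 6 in fish against lard. With the animal as a replicate block, on the animals with both tissues, the counts were 3 and 0. Without the 4 libraries that stood apart they were 1 and 7. In soy against control the difference of log2 fold changes was -3.64 for Osbpl3, -0.90 for Lgals8, 6.94 for Cux2, -3.84 for Scara5 and -1.52 for Arsg. In fish against lard it was -1.52 for Faah, -2.97 for Tbc1d31, 1.20 for Fbxo21, -3.32 for Acox2 and -0.78 for Lgals8, and all 5 calls were lost without fish liver 1067, fish muscle 1124, lard muscle 1100 or lard muscle 1101. In fish against lard muscle Acox2, Faah and Tbc1d31 were at 3.25, 1.39 and 1.99, against -0.16, -0.14 and -1.03 in liver. The exons of Arsg overlap Slc16a6 and those of Lgals8 overlap Heatr1, so both are uncertain.

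Signals also appeared in reads that the comparisons above do not use. In reads outside annotated exons 54 genes differed between soy and control liver, 8 between fish and control and 20 between lard and control. In muscle the counts were 2, 1 and 5. Mup15 and Mup17 were lower there in soy liver by -7.88 and -4.65, and Cyp2b13 and Cux2 higher by 4.67 and 5.16. In muscle Ttc7 and Prnd were at -2.03 and -1.86 in soy against control. Among genes without annotated exons 24 differed between soy and control liver, among them Gm11419 at -2.23, 2 between lard and control liver, and 1 between soy and control muscle, Gm11827 at 1.67.

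Soy livers 1073 and 1159 may stand apart for a technical reason tied to transcript length. Across genes their deviation from the liver mean had Spearman correlations with exon length of -0.648 and -0.629, beyond the 0.0614 to 0.34 of the other 13 livers, while for GC content the smaller was 0.198, which decides nothing. Removing both trends lowered the ribosomal median from 1.04 to 0.226 in 1073 and from 0.995 to 0.33 in 1159, so whether they are the whole cause stays open. No marker list summed in both to more than 0.842 of the highest other liver, which argues against a large excess of a listed cell type. For skeletal muscle and erythroid markers that highest liver, fish liver 1123 and lard liver 1130, was itself an outlier. A smaller excess could go unseen, and cell types without a list were not tested. The higher of both other soy livers was at -6.83 on the first component. This was part of the pattern as first seen, so an effect of the soy diet stays undecided. Library size did not set soy livers 1073 and 1159 apart. They held 18606459 and 16052305 exon reads, within the 11315231 to 21278699 of the other livers.

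Control muscles held more B and plasma cell marker reads than restricted muscles, with means of 234 and 71.6 CPM, and the cause stays open. Control muscle 1121 held the most at 321 CPM, of which Ighm alone gave 318.7 CPM. In control muscle 1095 Ighm gave 131.8 of 134 CPM, so these sums follow that gene. Neutrophil markers in 1121 summed to 1.41 CPM, against at most 3.22 in restricted muscles and at least 296 in control muscles 1071 and 1120. This argues against marrow or blood cells with neutrophils in 1121, but says nothing of other blood cells. Whether such cells in 1071 and 1120 carry the rest cannot be told: control muscle 1095 held 134 CPM against at most 125 in restricted muscles, a margin within the restricted SD of 29.9, and mean log2 levels of 1095 and 1121 of at most 1.34 lay below the highest restricted muscle at 1.42, while 1071 and 1120 were at 3.48 and 4.85. Calorie restriction cannot be told either: the exact permutation p of 0.0152 for 1095 and 1121 was fixed by values already seen and decides nothing. Lymphoid tissue carried with the controls is undecided, at a mean T and NK cell marker sum of 2.72 CPM against 0.827 in restricted muscles.

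Fish muscle 1124 held both keratinocyte and stress response transcripts, and no explanation could be decided. A state of the mouse in both tissues could not be told, as the stress genes had a median of 0.413 above the other fish livers in its liver. The fish diet could not be told, as fish muscle 1123 was at a mean log2 CPM of 4.74, above every soy and lard muscle, but fish muscle 1067 was at 2.15. Skin cells could not be told, as the next muscle held only 19.6% as many keratinocyte reads.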

How the results depend on the processing

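Chosen after the values were seen were all alternatives that leave out the libraries that stood apart, the share of reads outside exons as covariate, limma-voom with library weights, unique exon reads, and the fit of animals with both tissues without a block. Every named gene past the threshold kept its direction. These genes stayed past the threshold in 449 and lost it in 195 of the tests under the alternatives, and in 538 and 342 on removal of single libraries. Unless a cause is given, the cause was not tested. The smallest library held 11315231 exon reads, and genes below the count filter were not tested.

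Liver soy against control (149 genes) kept its size with DESeq2 size factors (149), limma-voom (157), no filter (144), a mean CPM of at least 5 (127) and unique exon reads (156). It was 866 with the DESeq2 Wald test, 31 with only the compared diets, 97 with the library number as block, 23 at a 1.5-fold threshold, 26 leaving out both soy livers that stand apart, 75 with the share of reads outside exons as covariate and 0 with library weights. Without single libraries it ranged from 34 to 1625. The cause was not tested.

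Liver fish against soy (12 genes) became 813 with the DESeq2 Wald test, 1 with only the compared diets, 4 with the library number as block, 0 at a 1.5-fold threshold, 0 leaving out both soy livers that stand apart, 2 with the covariate and 0 with library weights. Without single libraries it ranged from 0 to 2092. Liver lard against soy (0 genes) became 151 with the DESeq2 Wald test and ranged from 0 to 780 without single libraries. For these changes the cause was not tested.

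Liver fish against lard (26 genes) became 164 with the DESeq2 Wald test, 136 with only the compared diets, 13 with the library number as block, 0 at a 1.5-fold threshold, 98 leaving out both soy livers that stand apart, 76 with the covariate and 408 with library weights. Without single libraries it ranged from 0 to 43. Again the cause was not tested.

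Liver fish against control (49 genes) became 165 with the DESeq2 Wald test, 29 at a mean CPM of at least 5, 78 with only the compared diets, 26 with the library number as block, 18 at a 1.5-fold threshold, 137 leaving out both soy livers that stand apart, 149 with the covariate and 491 with library weights, and ranged from 15 to 81 without single libraries. Liver lard against control (65 genes) became 274, 166 with only the compared diets, 39 with the block, 14 at 1.5-fold, 236 leaving out both soy livers, 168 with the covariate and 597 with library weights, and ranged from 12 to 85. The cause was not tested.

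Muscle soy against control (0 genes) became 1 with DESeq2 size factors, 242 with the DESeq2 Wald test, 1 with no filter and 2 leaving out both control muscles that stand apart, and ranged from 0 to 9 without single libraries. Muscle fish against lard (0) became 14 with the DESeq2 Wald test and 1 with library weights, and ranged from 0 to 31. Muscle fish against control (1) became 395 with the DESeq2 Wald test, 0 at a mean CPM of at least 5, 0 with only the compared diets, 0 with the library number as block, 3 leaving out both control muscles, 3 with the covariate and 13 with library weights, and ranged from 0 to 69. Muscle lard against control (0) became 318 with the DESeq2 Wald test, 3 with no filter, 1 with only the compared diets, 1 with the covariate and 3 with library weights, and ranged from 0 to 28. Muscle fish against soy and lard against soy stayed at 0 under every alternative and removal. In both, the cause was not tested.

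The tissue difference in soy against control (103 genes) became 3 with the animal as replicate block and 7 with the same animals and no replicate block. Those animals leave out soy liver 1159 and control muscle 1071, which stand apart. Most of the fall came with this set, but fewer animals and the loss of those libraries cannot be told apart. The count was 27 with no filter, 283 at a mean CPM of at least 5 and 1 leaving out the 4 libraries that stand apart. It ranged from 3 to 1644 without single libraries. The tissue difference in fish against lard (6) was 0 with the animal as replicate block and 8 without it, and ranged from 0 to 41. That in fish against soy ranged from 0 to 5. Libraries of the same number had a median correlation of -0.02 in liver and -0.05 in muscle, against 0.01 and 0 for different numbers, so pairing by number does not show. Liver and muscle of one animal had a median correlation of 0.06 over 13 pairs, 5 of them above 0.1. No such value was computed for different animals, so pairing by animal cannot be told. Beyond this the cause was not tested.

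The muscle difference between fish and lard on the score (0.119) was 0.124 with score genes from DESeq2, 0.133 with genes scaled by SD, 0.175 with score genes from the soy and control libraries only and 0.187 leaving out both control muscles that stand apart, each past the threshold at an exact permutation p of 0.0286. It ranged from 0.065 to 0.263 without single libraries. In liver it kept its sign and stayed short of the threshold, from -0.154 to -0.051 under the other settings and from -0.161 to -0.019 without single libraries. The liver correlation of soy against control with fish against soy (-0.661) was -0.32 with the soy libraries split between both comparisons, which removes the shared libraries, -0.72 at a mean CPM of at least 5 and -0.566 leaving out both soy livers, and ranged from -0.759 to -0.593. The muscle correlation (-0.195) ranged from -0.364 to -0.085; the split was not run in muscle, with 3 soy libraries. In each case the cause was not tested.

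Of 77 liver list calls 2 remained in camera with an estimated correlation and 14 in fry, and of 67 muscle calls 0 and 0. With the library number as block there were 82 and 75. The directions of some camera calls turned when the libraries that stand apart were left out. In liver these were the proteasome in fish against soy (adjusted p 0.0752), lard against soy (0.439) and soy against control (0.788), and in lard against soy the ribosomal proteins (0.988) and oxidative phosphorylation (0.000546), by limma camera. In muscle they were the cell cycle in fish against control (0.583) and soy against control (0.797), and in lard against control the ribosomal proteins (7.39e-06) and the proteasome (0.571). The median of B and plasma cell markers in soy against control also turned, over 3 genes in place of 4, while the camera direction stayed down (adjusted p 0.322). Here too the cause was not tested.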

Other observations

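The test of restricted against control livers below was chosen after its result was seen. No prediction was written for the splits that keep both tissues of an animal together; those of the other tests were written first. Values of some lists against control are not given above. With lard, liver gluconeogenesis and amino acid breakdown genes had a median log2 fold change of 0.34 against control, with 2 of 27 higher (10 higher and 0 lower adjusted over the list alone; limma camera adjusted p = 0.0786 with an estimated correlation). With fish oil, 4 of 34 apolipoprotein and lipid transport genes were lower than in control (3 higher and 7 lower adjusted over the list alone; adjusted p = 0.748 with an estimated correlation). In muscle, circadian clock genes had a median of 0.33 with lard against control (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.574 with an estimated correlation).

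In reads of genes without annotated exons, Gm15441 was higher in fish than in lard livers by 3.20 ± 0.45 (log2 fold change ± SE, edgeR adjusted p = 0.00221). In reads outside annotated exons, Apoa4 was lower in fish than in lard livers by -3.39 ± 0.46 (edgeR adjusted p = 0.00806).

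The sex-biased pattern may be a response to calorie restriction whatever the fat. The mean log2 level of female-biased minus male-biased genes was -4.16 ± 0.36 (SD) in control, 0.40 ± 0.59 in soy, -1.08 ± 1.68 in fish and -0.03 ± 1.08 in lard livers. The highest control liver was at -3.82 and the lowest restricted liver, on fish oil, at -3.31. Restricted livers were higher by 3.92 (exact permutation p = 0.0022 over 455 splits), and by 3.84 without soy livers 1073 and 1159 (exact permutation p = 0.0035). Both p values are the smallest the splits allow. The lists had already been seen to differ in the same livers, so these p values decide nothing. A smaller shift with fish oil than with lard could not be told, at a difference of -1.06 (exact permutation p = 0.4).

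Other splits of the same libraries were tested to see how often a grouping by chance gives as many genes. In liver the real split alone reached its count, 1 of 35, in fish against soy, fish against lard, fish against control and lard against control, where the highest other split gave 1, 0, 4 and 2 genes. In liver soy against control 6 of 35 splits reached the count, up to 2802 genes, in splits that set soy livers 1073 and 1159 against most others, so that count could come from those libraries. Where the real count is 0 every split reaches it, so nothing is decided: this holds for liver lard against soy (35 of 35, highest other 2) and for muscle soy against control, lard against soy, fish against lard and lard against control (35 of 35 each, highest other 1073, 0, 13 and 6). It also holds for muscle fish against soy (10 of 10, highest other 31), where the splits are also too few. In muscle fish against control, with 1 gene, 6 of 35 reached it, up to 933 genes. For tissue differences the real count was reached by 8 of 97 splits in soy against control and 1 of 96 in fish against lard, and a count of 0 by 97 of 97 in fish against soy and 99 of 99 in lard against soy. Those splits regroup each tissue on its own. Splits that keep both tissues of an animal together gave 1 of 20 in soy against control, where the highest other count was 2. With 20 splits a share below 0.05 is out of reach. Control muscle 1071 and soy liver 1159 kept their diets in all 20, as each of these mice has 1 tissue here. Such splits cannot show how far those libraries make the count. In fish against lard they gave 1 of 35, with a highest other count of 2. The count of 0 was reached by 20 of 20 in fish against soy and 35 of 35 in lard against soy.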
